A study of Mus musculus with 4 samples.

How the data were processed

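Bulk RNA was sequenced from 4TO7 mouse breast carcinoma cells isolated from tumors in BALB/c mice, with 2 libraries from tumors resistant to anti-PD-L1 and 2 from control tumors. Per the labels' protocols, tumors were digested with hyaluronidase, collagenase, dispase and DNase, total RNA was extracted with a Qiagen kit, and libraries followed a standard Illumina protocol. The labels conflict on treatment: the treatment label of all 4 samples, resistant and control alike, says untreated, whereas their treatment protocol names the anti-PD-L1 antibody in vivo. What the control tumors received was not resolved, and whether counting used strand is not given in the sources used here. Groups were taken from the sample source labels, and columns were matched to samples by title. The deposited table holds log2 values, which are log2(count divided by a size factor per library, plus 1), made by the authors with STAR, DESeq2 and the mm10 genome per the submitters' processing notes, which give no versions or settings. The scale was worked out from the values: 2 to the deposited value, minus 1, fell on whole multiples of 1 step per library for 100% of values in each library, at a tolerance of 0.01 reads. Dividing by that step gave the reads per gene, and so the depth of 46999812, 45666470, 49592054 and 46179416 reads.

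The table lists 55385 genes by versioned Ensembl identifier, of which 28603 had no read in any library. Symbols were joined on the identifier without its version for 55144 of them, and 54487 matched with the version. Coordinates are those of GENCODE M21 on GRCm38, which is mm10. Genes with a mean of at least 10 normalized counts over the 4 libraries were tested, 14238 in all. Differences between resistant and control were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend, no block), on the deposited values as they are, since these already carry a pseudocount of 1, and adjusted by the Benjamini-Hochberg method at a threshold of 0.05. The plan had assumed unlogged values and the same transformation. Fold changes on that scale understate the change of low genes. Values are given as normalized counts (mean ± SD, n = 2) and as log2 fold changes, resistant minus control, ± SE. Exon overlaps were found with GenomicRanges 1.54.1.

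Gene lists, the rule for named genes, the tests and most alternatives were fixed before the data were examined. The 37 lists cover MHC class I, non-classical class I and class II presentation, the constitutive proteasome, interferon gamma and type I interferon responses, nucleic acid sensing, checkpoint ligands, chemokines, NF-kappaB, TGF-beta, mesenchymal, epithelial, luminal, stem cell and Wnt genes, proliferation, Myc targets, hypoxia, oxidative phosphorylation, the unfolded protein response, p53, cholesterol and NRF2 genes, markers of 10 other cell types, immediate early genes, mitochondrially encoded genes and ribosomal proteins. Lists came from general knowledge and not from these libraries. A list with at least 5 tested genes (32 lists) was tested two-sided with limma camera at a preset inter-gene correlation of 0.01, adjusted over these lists. 11 passed, 5 upward and 6 downward. With an estimated correlation camera passed 0, the lowest adjusted p being 0.564 and 2 lists lying under an unadjusted p of 0.05, and with fry 5 passed, all of which also passed camera: MHC class I, non-classical class I, both interferon lists, and pericytes and muscle. The named genes were the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 100 in the higher group and groups that did not overlap, leaving out predicted gene models, pseudogenes and genes with no symbol; Lcor and the MHC class I list; up to 4 genes with the smallest p from each list that passed or had members past the threshold; and up to 3 genes with the highest mean from each list of cell type or quality markers.

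Counting intervals (95%, exact binomial for ratios of reads and for shares) and floors of 3 reads cover counting error only, since PCR reads without molecular identifiers are not independent molecules. Alternatives were other pseudocounts, filters, scalings, robust moderation (with limma cameraPR on the moderated statistics for lists), a block for the replicate number and leaving out each library, which leaves 1 library in a group whose spread is taken from the other group. A call lost or gained in such a fit can thus reflect that spread and not the library left out. The planned count models were not run. A limma voom fit on the recovered reads was added after seeing the data. The fitting steps were tested on simulated reads for 14238 genes with 200 changed genes: at folds of 1.5, 2, 4 and 8, 70%, 82%, 100% and 98% of 50 genes each were called, with 8 unchanged genes. A simulated list shifted downward had camera adjusted p = 4.05e-26 with the preset correlation, and adjusted p = 0.238 with an estimated one. The estimated setting thus missed a shift that was present. The simulated genes were independent, so the simulation does not show how the preset correlation behaves where the genes of a list vary together. Figures were drawn with matplotlib 3.10.9.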

Results

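Gene expression was measured by bulk RNA sequencing in 4TO7 cells, a mouse mammary carcinoma line, isolated from tumors grown in BALB/c mice. 2 libraries came from tumors resistant to anti-PD-L1, an antibody that blocks the checkpoint ligand PD-L1, and 2 came from control tumors. The libraries held 46999812 (resistant replicate 1), 45666470 (resistant replicate 2), 49592054 (control replicate 1) and 46179416 (control replicate 2) counted reads. The most abundant transcript, Spp1, took 1.83%, 2.04%, 2.09% and 1.37% of them. Across genes, log2 values correlated with r = 0.995 between the resistant libraries and r = 0.989 between the control libraries. The standard deviation of the log2 difference was 0.31 within the resistant pair, 0.45 within the control pair and 0.65 to 0.72 between libraries of different groups. The replicates differed by more than sampling noise, with a chi-square per degree of freedom of 20.6 in the resistant pair and 66.4 in the control pair. A first principal component that separated the groups carried 73.0% of the variance, and a second that separated the control libraries carried 20.2%. Nothing in the labels says that the libraries of a group came from separate animals, so p-values measure only the spread between these libraries.

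The first comparison asked which genes differed between resistant and control tumor cells. Resistant cells had gained transcripts of the piRNA-pathway helicase Mov10l1, the slow skeletal troponin Tnni1, the acyl-CoA synthetase Acsbg1 and the secreted serpin Serpinf1, and had lost most transcripts of the GPI-anchored protein Ly6e, the X-linked homeobox gene Rhox5, the X-linked gene Xlr3a and the interferon-inducible GTPase Iigp1. In limma, 758 genes rose and 674 fell in the resistant libraries among 14238 tested, and 317 and 390 of these changed at least 2-fold. Mov10l1 (ENSMUSG00000015365.15, chromosome 15, 88982909 to 89055152, GRCm38) had 447 ± 45.7 normalized counts in resistant cells (SD, n = 2) and 0 reads in both control libraries. Counted against a floor of 3 reads per control library, it was at least 151-fold higher. Serpinf1 rose from 227 ± 48.5 to 2084 ± 279 normalized counts, a log2 fold change of 3.20 ± 0.19 (SE, adjusted p = 0.000336). Acsbg1 (3.76 ± 0.23), Tnni1 (3.81 ± 0.24), the neuromuscular acetylcholine receptor subunit Chrnd (3.19 ± 0.27), the kelch protein Klhl30 (3.57 ± 0.31), Mgarp (3.37 ± 0.29), Adgra2 (3.32 ± 0.25), Asgr1 (3.23 ± 0.30) and the cytokine receptor subunit Csf2rb2 (4.39 ± 0.36) completed the 10 largest rises. Csf2rb2 has a close paralog, Csf2rb, with which reads can be shared.

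Ly6e (ENSMUSG00000022587.14, chromosome 15, 74955051 to 74959905) fell from 1628 ± 465 normalized counts in control to 21.1 ± 9.63 in resistant cells, a log2 fold change of -6.25 ± 0.34 (adjusted p = 0.000336). Rhox5 (ENSMUSG00000095180.8, chromosome X, 37804842 to 37808876) fell from 1603 ± 392 to 22.98 ± 0.646 normalized counts, or -6.04 ± 0.23 (adjusted p = 5.94e-05). Xlr3a, which has near-identical copies on the X chromosome, changed by -3.51 ± 0.17. Iigp1 changed by -4.05 ± 0.24, the adaptor Efs by -3.96 ± 0.31, the sulfotransferase Hs3st1 by -3.57 ± 0.37, the epithelial transcription factor gene Tfap2c by -4.38 ± 0.46 and the interferon-inducible GTPase Tgtp2 by -3.42 ± 0.47. The mucus protein gene Fcgbp and the gene for the peptide hormone cholecystokinin, Cck, had only 4 reads each over both resistant libraries. Their ratios of control to resistant reads were 141 (95% exact interval 54.7 to 518) for Fcgbp and 54.4 (21.0 to 201) for Cck, intervals that cover counting error only. In all 1432 called genes the 2 groups did not overlap, which held for 56.7% of the tested genes, against 33.3% by chance. Leaving out a resistant library lowered the number of calls, and leaving out a control library raised it. The spread then came from the 2 libraries of the other group alone. The control pair varied more than the resistant pair (standard deviation of the log2 difference 0.45 against 0.31). Without a filter on low values, 126 genes rose and 185 fell.

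**Figure D1:**
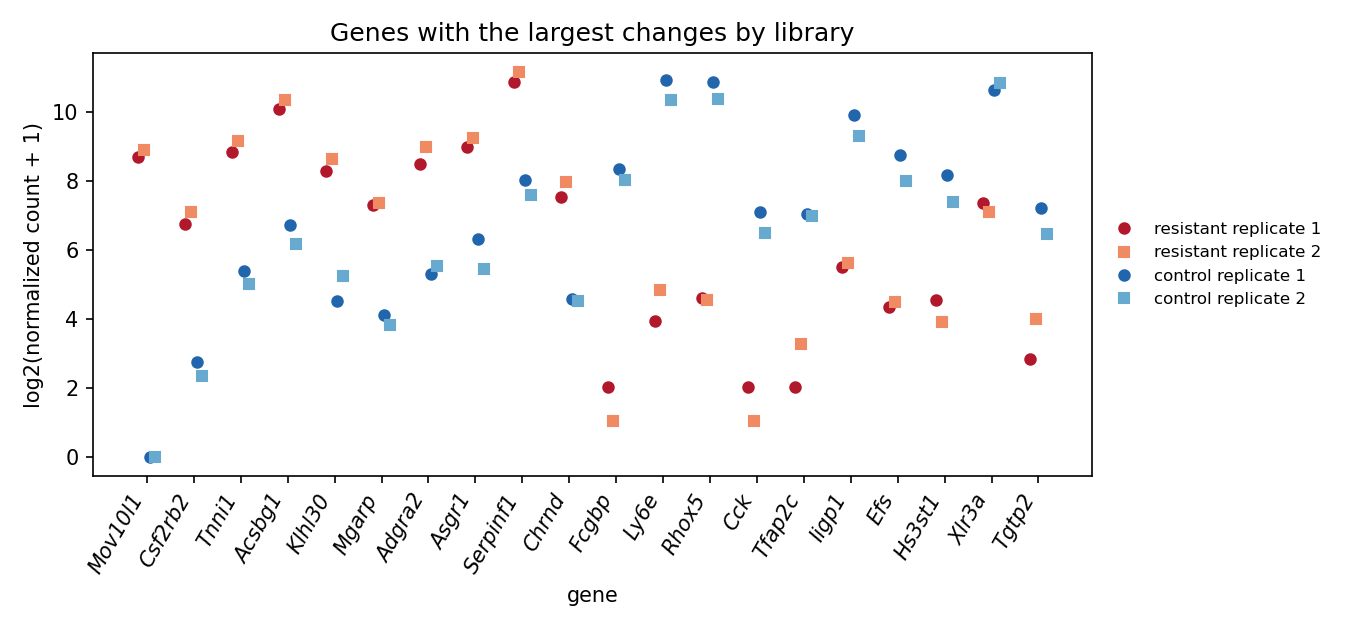
The vertical axis gives log2(normalized count + 1) for the 10 genes with the largest rise and the 10 with the largest fall, and each point is 1 library (red and orange resistant, blue control). Both resistant libraries lie on the same side of both control libraries for each of the 20 genes, which the rule that chose them required. Mov10l1 sits at 0 in both controls.

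The series addresses antigen presentation, so the MHC class I pathway, which loads peptides onto class I molecules for display to CD8 T cells, was the main gene group. Its transcripts were modestly lower in resistant cells: the median log2 fold change of 17 measured genes was -0.33, and both resistant libraries lay below both controls for 15 of them. 4 genes fell, namely the peptide transporter subunit Tap1 (-0.65 ± 0.11, adjusted p = 0.014), the loading factor Tapbp (-0.54 ± 0.11, adjusted p = 0.023), the immunoproteasome subunit Psmb9 (-0.53 ± 0.13, adjusted p = 0.0428) and the peptide-trimming enzyme Erap1 (-0.49 ± 0.11, adjusted p = 0.035). Tap1 (ENSMUSG00000037321.17, chromosome 17, 34187553 to 34197225) went from 2508 ± 37.5 normalized counts in control to 1599 ± 96.3 in resistant cells. The other 13 genes did not pass, 4 genes fell when p was adjusted over the list alone, and 1 gene, Pdia3, had a positive value (0.20 ± 0.12). The class I heavy chains H2-K1 and H2-D1 had values of -0.35 ± 0.12 (adjusted p = 0.121) and -0.32 ± 0.14 (adjusted p = 0.213), and the light chain B2m had -0.06 ± 0.15 (adjusted p = 0.831). H2-K1 stood at 45879 ± 335 normalized counts in resistant cells and B2m at 101758 ± 8173. In the set test the list was lower (limma camera, adjusted p = 9.7e-05; adjusted p = 0.564 with an estimated correlation), and fry, which tests whether the genes move on balance one way, gave adjusted p = 0.0388.

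Each of the 4 class I calls ended when 1 resistant library was left out, where the spread came from the control pair alone. The log2 fold changes without resistant replicate 1 and 2 were -0.59 and -0.71 for Tap1 and -0.50 and -0.58 for Tapbp. They were -0.52 and -0.53 for Psmb9 and -0.56 and -0.42 for Erap1. All 4 calls also ended with no filter on low values, and a block for the replicate number, which only names samples, ended those of Tapbp, Psmb9 and Erap1. The median of the 17 genes was -0.34 without resistant replicate 1 and -0.32 without resistant replicate 2. It was -0.25 without control replicate 1 and -0.37 without control replicate 2. BALB/c mice carry another MHC haplotype than the reference genome, so reads of H2-K1 and H2-D1 are uncertain, and exons of Tap1 and Psmb9 overlap on opposite strands, which cannot be told apart where counting ignores strand. Exons of Tapbp overlap those of Zbtb22 on the same strand, so reads can be shared. Lcor, a nuclear receptor corepressor studied as a regulator of antigen presentation genes, had 1493 ± 63.6 normalized counts in resistant and 1745 ± 285 in control cells (ENSMUSG00000025019.17, chromosome 19, 41482637 to 41562261). The 106 tested genes of its 10 Mb window, chromosome 19 at 40 to 50 Mb, had a median log2 fold change of -0.22. Lcor's own log2 fold change of -0.22 ± 0.14 did not stand out from that median and did not pass (adjusted p = 0.385). It was -0.38 (adjusted p = 0.034) without control replicate 1 and -0.05 (adjusted p = 0.847) without control replicate 2. Nlrc5, the transactivator of class I genes, did not pass either (-0.24 ± 0.13, adjusted p = 0.279).

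**Figure D2:**
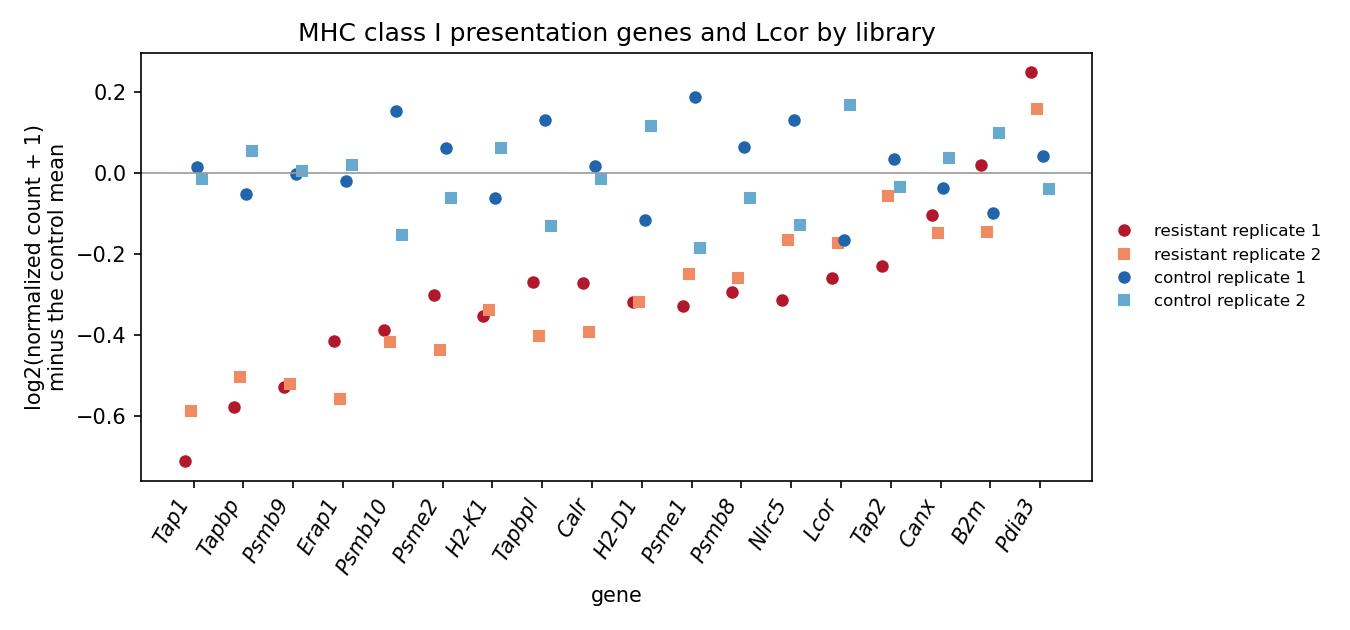
The vertical axis gives each library's log2(normalized count + 1) minus the mean of the 2 control libraries, for the 17 MHC class I presentation genes and Lcor. Resistant libraries (red and orange) lie furthest below control (blue) for Tap1, Tapbp, Psmb9 and Erap1, while for B2m the groups overlap.

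Interferon-stimulated genes fell together in resistant cells. Of 46 genes of the type I interferon response, 41 fell and none rose, with a median log2 fold change of -1.61. Among them were the ubiquitin-like modifier Isg15 (-1.77 ± 0.11), the 2'-5'-oligoadenylate synthetase Oas3 (-2.30 ± 0.15), the ADP-ribosyltransferase Parp14 (-1.97 ± 0.12) and Rtp4 (-1.78 ± 0.11). Isg15 (ENSMUSG00000035692.7, chromosome 4, 156199424 to 156200818) went from 5928 ± 460 normalized counts in control to 1737 ± 52.5 in resistant cells (adjusted p = 0.000343). Of 29 genes of interferon gamma signalling, which shares no gene with the type I list, 17 fell and none rose, with a median of -1.48. They included the guanylate-binding proteins Gbp3 (-2.72 ± 0.16) and Gbp7 (-1.64 ± 0.13), the GTPase Ifi47 (-2.50 ± 0.17) and Iigp1. Adjusted over the list alone, 43 and 21 genes fell. Both lists were lower in the set test, with adjusted p = 1.69e-39 for type I and 1.16e-17 for interferon gamma, and adjusted p = 0.564 with an estimated correlation for each. Fry gave adjusted p = 0.0388 for both. Of the 75 genes in these lists, 52 fell without resistant replicate 1 and 50 without resistant replicate 2. Guanylate-binding proteins and interferon-inducible GTPases are gene families with close paralogs, so reads can be split between members.

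Some non-classical MHC class I genes and some nucleic acid sensors fell as well. Of 14 non-classical MHC class I genes, 7 fell and none rose, with a median of -0.55: H2-T24 (-2.13 ± 0.20), H2-Q4 (-0.82 ± 0.10), H2-Q6 (-0.73 ± 0.11) and H2-T23 (-0.71 ± 0.14) had the smallest p. Adjusted over the list alone, 10 fell (set test adjusted p = 1.79e-06; adjusted p = 0.564 with an estimated correlation). With either resistant library left out 2 of the 14 passed, and the calls of H2-Q6 and H2-T23 ended. These are near-identical paralogs of the MHC region, so single values are uncertain. Of 13 genes for cytosolic DNA and RNA sensing, 5 fell and none rose, also 5 adjusted over the list alone, among them the RNA sensors Ddx58 (-1.62 ± 0.11), Ifih1 (-1.03 ± 0.11) and Dhx58 and the RNA editor Adar (-1.11 ± 0.10). 3 genes of that list also belong to the type I list, its median was -0.10, and the set test gave adjusted p = 0.0024 (adjusted p = 0.569 with an estimated correlation; fry adjusted p = 0.071). Of 8 MHC class II genes, H2-Ab1 (-1.86 ± 0.31) and its transactivator Ciita (-2.07 ± 0.46) fell at low levels, 220 ± 78.5 and 59.1 ± 26.5 normalized counts in control cells. Adjusted over the list alone, 1 rose and 4 fell, and the list did not pass the set test (adjusted p = 0.51). When either resistant library was left out 1 class II gene fell and none rose, and when either control was left out 3 fell and 1 rose. The H2-Ab1 call ended without resistant replicate 2 and the Ciita call without resistant replicate 1. Beside these groups, Ptprc, which encodes the pan-leukocyte antigen CD45, had means of 1.07 normalized counts in resistant and 1.46 in control cells.

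Inflammatory genes changed in part. Of 26 NF-kappaB response genes, 7 fell and 1 rose, with a median of -0.16 (8 fell and 1 rose adjusted over the list alone). The list passed the limma camera test (adjusted p = 0.00374, but 0.58 with an estimated correlation). It did not pass fry (adjusted p = 0.106). The inhibitor Nfkbia fell by 1.13 ± 0.12 and the adhesion molecule Icam1 by 1.47 ± 0.23 on the log2 scale, as did the subunit genes Relb (-0.65 ± 0.12) and Nfkb1 (-0.54 ± 0.11). With resistant replicate 1 or 2 left out, 1 and 2 of the 26 genes fell and none rose, and with control replicate 1 or 2 left out, 10 and 11 fell and 2 rose. The calls of Relb and Nfkb1 ended when either resistant library was left out and that of Icam1 without resistant replicate 1. Of 22 chemokine and cytokine genes, 6 fell and 1 rose (8 and 4 adjusted over the list alone). The neutrophil chemoattractants Cxcl1 (-1.54 ± 0.14) and Cxcl3 (-1.57 ± 0.26) and Il15 (-0.89 ± 0.17) fell, and the interleukin-23 subunit Il23a rose (1.00 ± 0.17). The median of that list was 0.01 and the test pointed down without passing (adjusted p = 0.318), but it passed without control replicate 2 (adjusted p = 0.0246). When either resistant library was left out, 2 chemokine and cytokine genes fell and none rose, and with control replicate 1 or 2 left out, 6 and 5 rose and 7 and 8 fell. The calls of Il15 and Il23a ended when either resistant library was left out.

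Of 21 checkpoint and immune ligands, 4 rose and 3 fell (4 and 4 adjusted over the list alone; set test adjusted p = 0.782). The inhibitory ligand Vtcn1, also called B7-H4, rose from 30.2 ± 15.7 to 201 ± 9.50 normalized counts (log2 fold change 2.79 ± 0.37, adjusted p = 0.00488). The TIGIT ligand Pvr (0.98 ± 0.12) and the adenosine-producing ectonucleotidase Nt5e, or CD73 (1.07 ± 0.17), rose to 16747 ± 483 and 34410 ± 2209 normalized counts. When either resistant library was left out 3 rose and none fell, and without control replicate 2, 4 rose and 5 fell. The death receptor Fas fell (-1.19 ± 0.17), a call that ended when either resistant library was left out. Cd274, which encodes PD-L1 itself and is named here outside the rule for named genes, had 330 ± 35.4 normalized counts in resistant and 526 ± 105 in control cells and did not pass (-0.66 ± 0.19, adjusted p = 0.0772).

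Some genes of hypoxia and glycolysis, of ribosome biogenesis and of the respiratory chain rose in resistant cells. Of 35 hypoxia and glycolysis genes, 8 rose and none fell (14 adjusted over the list alone), with a median of 0.31. Carbonic anhydrase 12, Car12 (ENSMUSG00000032373.15, chromosome 9, 66713686 to 66766845), rose from 804 ± 19.3 to 5863 ± 140 normalized counts (2.86 ± 0.11, adjusted p = 5.94e-05). The oxidoreductase Ero1l (0.97 ± 0.11), enolase 2, Eno2 (0.93 ± 0.12), and Ndrg1 (0.79 ± 0.11) rose as well. Of 38 Myc target and ribosome biogenesis genes, 5 rose and none fell (13 adjusted over the list alone), with a median of 0.26, among them the pyrimidine synthesis gene Cad (0.74 ± 0.14), the spermidine synthase Srm (0.52 ± 0.10), Ppan (0.55 ± 0.11) and Rrp9 (0.62 ± 0.13). Myc itself rose by 0.63 ± 0.14. Myc and Ndrg1 lie at 60 to 70 Mb of chromosome 15, where 21 tested genes, themselves included, had a median of 0.59. The rise of Myc did not stand out from that median, so it may follow its neighbours. Of 63 nuclear oxidative phosphorylation genes, 5 rose and none fell (5 adjusted over the list alone), with a median of 0.12, led by Ndufb9 (0.69 ± 0.14), Ndufv2 (0.46 ± 0.10), Ndufa4 (0.49 ± 0.12) and Uqcrc1 (0.42 ± 0.10).

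The set tests of these 3 lists gave adjusted p = 3.46e-08, 5.2e-06 and 0.00272, and adjusted p = 0.569, 0.752 and 0.83 with an estimated correlation. Fry did not pass them (adjusted p = 0.0928, 0.236 and 0.236). The oxidative phosphorylation list no longer passed without resistant replicate 1 (adjusted p = 0.074) or without control replicate 1 (adjusted p = 0.0918). Of the hypoxia genes, 6 rose without resistant replicate 1, 3 without resistant replicate 2, 21 without control replicate 1 and 13 (with 1 lower) without control replicate 2. With control replicate 1 or 2 left out, 12 and 19 Myc target genes rose and 1 fell in each case, and 11 (with 1 lower) and 16 oxidative phosphorylation genes rose. With resistant replicate 1 or 2 left out, 0 and 1 of the oxidative phosphorylation genes rose in limma, against 4 and 9 at an unadjusted p under 0.05. Car12, Ero1l and Eno2 kept their calls under each left-out library, Ndrg1 lost its call without resistant replicate 2, and none of the Myc target genes passed when either resistant library was left out (8 and 11 did at an unadjusted p under 0.05). Leaving out either resistant library also ended the calls of Myc, Ndufv2, Ndufa4 and Uqcrc1, rescaling to equal totals ended the last 2, and Ndufb9 lost its call without resistant replicate 1. Beside these lists, 7 of 9 mitochondrially encoded genes rose and none fell (9 adjusted over the list alone), with a median of 0.82 (set test adjusted p = 1.5e-06; adjusted p = 0.58 with an estimated correlation; fry adjusted p = 0.133). With resistant replicate 1 or 2 left out, 2 and 1 of the 9 passed. The cytochrome oxidase subunit mt-Co1 rose by 1.17 ± 0.14 and mt-Nd5 by 1.01 ± 0.14, and both calls ended without resistant replicate 2. Mitochondrial transcripts took 0.878% (95% exact interval 0.875 to 0.881) and 0.969% (0.967 to 0.972) of the reads in the resistant libraries, and 0.536% (0.534 to 0.538) and 0.429% (0.427 to 0.431) in the control libraries. The list of mitochondrially encoded genes was set in advance among the quality markers and not as a pathway. Whether its rise reflects sample handling was not tested.

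Lineage genes changed singly in both directions. Of 37 mesenchymal and matrix genes, 4 rose and 4 fell, also adjusted over the list alone: the collagens Col5a1 (1.64 ± 0.14) and Col6a3 (1.75 ± 0.16) rose, and the proteoglycan Dcn (-1.99 ± 0.24) and the protease inhibitor Timp3 (-0.89 ± 0.13) fell. Of 29 epithelial genes, 4 rose and 6 fell (5 and 8 adjusted over the list alone). Keratin 19, Krt19 (2.97 ± 0.25), and the claudin Cldn4 (1.95 ± 0.29) rose, whereas the claudins Cldn3 (-3.96 ± 0.41, 5 reads over both resistant libraries) and Cldn7 (-2.61 ± 0.40) fell. Of 31 TGF-beta response genes, 4 rose and 2 fell (5 and 2 adjusted over the list alone), with Ltbp2 (2.24 ± 0.19) and Inhba (0.68 ± 0.13) higher and the integrin Itgb8 (-1.55 ± 0.23) lower. That list had a median of 0.20 and adjusted p = 0.0559, and passed with a minimum mean of 50 (adjusted p = 0.0441), with a replicate block (adjusted p = 0.0476), and without resistant replicate 1 (adjusted p = 0.00847) or control replicate 1 (adjusted p = 0.00669). Of 26 stem cell associated genes, 5 rose and 2 fell, also adjusted over the list alone, including Lgr4 (0.78 ± 0.12), Procr (0.59 ± 0.10) and Notch3 (0.93 ± 0.18) upward and Ly6a, or Sca-1 (-3.43 ± 0.42), downward. Of 14 Wnt target genes, 3 rose and 2 fell (4 and 2 adjusted over the list alone), among them Tnfrsf19 (2.83-fold higher), Axin2 (2.00 ± 0.38), Tcf7 (-1.17 ± 0.19) and the Wnt deacylase Notum (-1.14 ± 0.24). In the mammary luminal lineage list of 11 genes, 1 gene, the EGF receptor ligand Areg, rose (1.03 ± 0.21), also adjusted over the list alone. None of the mesenchymal, epithelial, stem cell, Wnt and luminal lists passed the set test (adjusted p = 0.89, 0.51, 0.195, 0.833 and 0.51), although the stem cell list did without control replicate 1 (adjusted p = 0.0414). The median and the test differed in sign for the mesenchymal and Wnt lists. Calls of Inhba, Itgb8, Lgr4, Procr, Notch3, Axin2, Tcf7 and Areg ended when either resistant library was left out, those of Timp3 and Notum without resistant replicate 1, and that of Cldn4 without resistant replicate 2. The counts per list moved too. For the TGF-beta list, 1 gene rose and none fell when either resistant library was left out, against 10 and 3 without control replicate 1 and 7 and 4 without control replicate 2. Stem cell associated genes gave 1 higher and 1 lower without resistant replicate 1, 0 (5 at an unadjusted p under 0.05) and 1 without resistant replicate 2, 8 and 4 without control replicate 1, and 6 and 4 without control replicate 2. In the same order of libraries, higher and lower genes numbered 3 and 1, 2 and 2, 7 and 8, and 7 and 7 in the mesenchymal list, and 3 and 3, 1 and 3, 6 and 7, and 7 and 10 in the epithelial list. Wnt target genes gave 1 and 0 (2 lower at an unadjusted p under 0.05), 1 and 1, 4 and 2, and 4 and 5 in that order. No luminal gene passed when either resistant library was left out (1 rose, and 0 and 3 fell, at an unadjusted p under 0.05), while 2 rose without control replicate 1, and 1 rose and 6 fell without control replicate 2.

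With all libraries, none of 6 lists of cell division, stress and metabolism genes passed the limma set test. Of 58 proliferation genes, the replication genes Mcm4 (-0.47 ± 0.10) and Mcm3 (-0.47 ± 0.11) and the transcription factor gene E2f1 (-0.44 ± 0.11) fell, none rose, and 0 passed adjusted over the list alone in limma, against 7 at an unadjusted p under 0.05, where the list median was 0.00 (set test adjusted p = 0.749, but 0.014 without control replicate 1). Without control replicate 1, 2 proliferation genes rose and 15 fell, and without control replicate 2, 14 rose and 9 fell. None passed when either resistant library was left out, against 3 and 4 at an unadjusted p under 0.05. Of 35 genes of the unfolded protein and integrated stress response, 7 rose and 1 fell, also adjusted over the list alone, with Chac1 (0.76 ± 0.10), Asns (0.69 ± 0.12) and Atf3 (0.83 ± 0.16) higher and the secreted glycoprotein Stc2 (-2.77 ± 0.30) lower (set test adjusted p = 0.351). Of 24 p53 targets, Gadd45a rose (1.27 ± 0.12), and Perp (-1.36 ± 0.11) and Fas fell, the same numbers as adjusted over the list alone (adjusted p = 0.822). Of 27 NRF2 antioxidant genes, the glutathione synthesis gene Gclc (0.71 ± 0.13), the cystine transporter Slc7a11 (0.80 ± 0.17) and Mgst1 (0.66 ± 0.16) rose, 3 also adjusted over the list alone (adjusted p = 0.328). Of 23 cholesterol synthesis genes, 1 rose, also adjusted over the list alone, the squalene epoxidase Sqle (0.88 ± 0.13), and of 32 constitutive proteasome genes likewise 1, Psmb1 (0.53 ± 0.11), with adjusted p = 0.929 and 0.41 for the lists. The median and the test differed in sign for the proliferation and cholesterol lists. Calls of Mcm4, Mcm3, E2f1, Chac1, Gclc, Slc7a11, Mgst1 and Psmb1 ended when either resistant library was left out, and those of Asns, Atf3 and Sqle without resistant replicate 1. In the unfolded protein and integrated stress response list, 0 genes rose (5 at an unadjusted p under 0.05) and 1 fell without resistant replicate 1, 2 rose and 1 fell without resistant replicate 2, 10 and 2 without control replicate 1, and 9 and 6 without control replicate 2. For p53 targets 1 rose and 1 fell when either resistant library was left out, 4 and 3 without control replicate 1, and 6 and 2 without control replicate 2. No NRF2 or proteasome gene passed when either resistant library was left out (3 and 1 rose at an unadjusted p under 0.05). Without control replicate 1, 3 NRF2 genes rose and 3 fell, and without control replicate 2, 3 proteasome genes rose. The cholesterol list had 0 higher genes without resistant replicate 1 (1 at an unadjusted p under 0.05), 2 without control replicate 1, and 3 higher and 2 lower without control replicate 2.

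Markers of other cell types were examined to describe RNA from cells other than carcinoma cells. Most leukocyte markers were near 0 in all libraries: 28 of 30 T and NK cell markers, 12 of 13 B cell markers, 22 of 27 macrophage and monocyte markers, 13 of 16 neutrophil markers and 7 of 12 dendritic cell markers had means under 10 normalized counts. The markers above that level were present without the rest of their lists. Lck had 241 ± 16.4 normalized counts in resistant and 286 ± 12.6 in control cells, without the T cell receptor constant genes Trbc1 and Trbc2, which had 0 reads in all libraries. Itgb2 had 20632 ± 2504 and 16471 ± 5324, while C1qa had 0 reads. Cd68 rose (1.18 ± 0.27), Cd14 (-0.92 ± 0.20) and Mpeg1 (-2.65 ± 0.34) fell, and the macrophage list of 5 tested genes did not pass (adjusted p = 0.717; 1 rose and 2 fell adjusted over the list alone). In the dendritic cell list of 5 genes, Ccr7 (3.12 ± 0.29) and Batf3 (1.18 ± 0.24) rose and Bst2 (-1.19 ± 0.10), which is also interferon-inducible, and Zbtb46 (-2.52 ± 0.26) fell (adjusted p = 0.887; 3 rose and 2 fell adjusted over the list alone). 5 lists had fewer than 5 tested genes and no set test. Of these, the T and NK cell list had 2, Lck and Cd5 (2.01 ± 0.52, adjusted p = 0.0527), of which Cd5 passed adjusted over the list alone, the B cell list had 1 (Pax5 fell, -4.05 ± 0.65, with 2 reads over both resistant libraries), the neutrophil list 3 (Mmp9 rose, 0.71 ± 0.16), the adipocyte list 2 (Plin4 fell, -1.32 ± 0.31) and the erythroid list 1 (Klf1, -0.10 ± 0.45, adjusted p = 0.914). Adjusted over the list alone, Pax5, Mmp9 and Plin4 kept their calls, and 1 more adipocyte gene, Fabp4 (1.48 ± 0.54), passed. Calls of Cd68, Cd14, Batf3 and Mmp9 ended when either resistant library was left out and that of Plin4 without resistant replicate 1. When either resistant library was left out, 1 macrophage gene fell and none rose, and 1 dendritic cell gene rose. When either control was left out, 2 macrophage and 3 dendritic cell genes rose. Without control replicate 2, 2 neutrophil genes fell, and without control replicate 1, 1 adipocyte gene rose. Cd5 passed when either control was left out.

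Means under 10 normalized counts were found for 5 of 15 pericyte and muscle, 10 of 24 fibroblast and 14 of 21 endothelial markers. Of 10 tested genes of the pericyte and muscle list, 5 rose and none fell (5 and 1 adjusted over the list alone), with a median of 0.92. The list did not move as a whole: Rgs5 had means of 114 normalized counts in resistant and 120 in control cells, and Abcc9 had 4.67 and 16.6. Mcam rose from 1096 ± 252 to 3833 ± 624 normalized counts (1.82 ± 0.18), and the muscle filament gene Des (2.08 ± 0.27), Tnnt3 (1.68 ± 0.26) and Notch3 rose too (set test adjusted p = 0.0076; adjusted p = 0.564 with an estimated correlation; fry adjusted p = 0.00214). Of 14 fibroblast genes, Pdgfrb rose (1.00 ± 0.20) and Dcn fell (2 and 1 adjusted over the list alone; set test adjusted p = 0.328). When either resistant library was left out, 1 fibroblast gene fell and none rose (7 and 2 rose at an unadjusted p under 0.05), while 7 rose and 4 fell without control replicate 1, and 4 rose and 1 fell without control replicate 2. Col1a2 had 76.7 normalized counts in control replicate 2 against 1.02, 1.07 and 0.961 in the other libraries, while Col1a1 had 33.6 and 35.4 in the resistant and 12.5 and 69.6 in the control libraries. Of 7 endothelial genes, Vwf rose (2.45 ± 0.38), 1 also adjusted over the list alone, with Pecam1 at 13.1 ± 0.266 and 18.1 ± 4.25 normalized counts (adjusted p = 0.661, the median of -0.04 opposite in sign to the test). Without control replicate 1, 2 endothelial genes rose, and without control replicate 2, 1 rose and 1 fell. The median and the test also differed in sign for the macrophage list. When either resistant library was left out, 2 of the pericyte and muscle genes rose. The Tnnt3 and Pdgfrb calls ended when either resistant library was left out.

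Among genes that report on sample handling, 3 of 27 immediate early and heat shock genes rose and 2 fell, also adjusted over the list alone. The small heat shock protein gene Hspb1 rose (2.72 ± 0.25), and Egr1 fell from 837 ± 326 to 136 ± 16.0 normalized counts (-2.56 ± 0.27). The list did not pass (adjusted p = 0.909, the median of -0.04 opposite in sign to the test). Without resistant replicate 1, 1 of the 27 genes rose and 1 fell, without resistant replicate 2, 2 and 1, without control replicate 1, 6 and 3, and without control replicate 2, 7 and 6. Of 62 cytosolic ribosomal protein genes, Rpl37 (0.49 ± 0.11) and Rpl32 (0.41 ± 0.10) rose and Fau (-0.76 ± 0.18) fell, 0 passed adjusted over the list alone against 8 at an unadjusted p under 0.05, and the limma set test gave adjusted p = 0.425. Without resistant replicate 2 and without control replicate 2 that test gave adjusted p = 0.0276 and 0.0349. Without control replicate 1, 3 ribosomal protein genes rose and 6 fell, and without control replicate 2, 10 rose and 2 fell. None passed when either resistant library was left out, against 1 and 5 at an unadjusted p under 0.05. The Rpl37, Rpl32 and Fau calls ended when either resistant library was left out, and that of Rpl32 also under either rescaling.

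**Figure D3:**
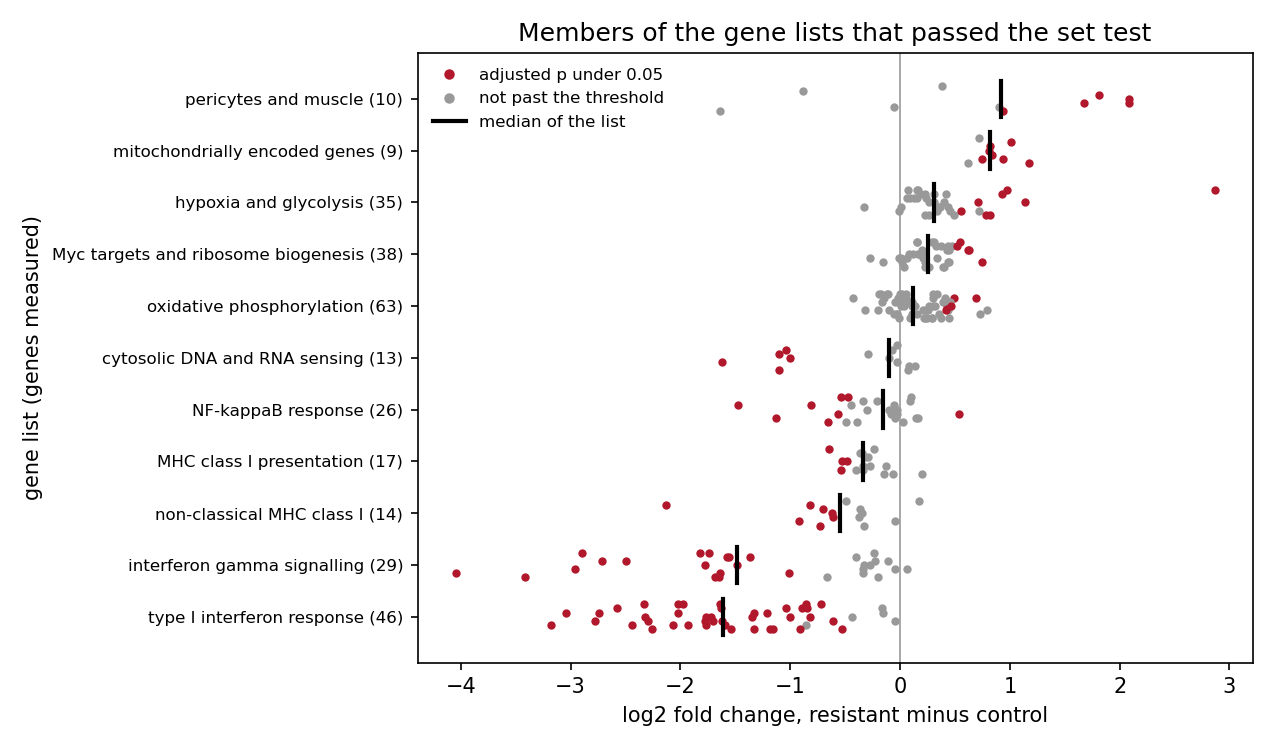
The horizontal axis gives the log2 fold change, resistant minus control, of each measured gene in the 11 lists that passed the set test, with red points for genes that passed and black bars for list medians. The type I interferon list has the lowest median, -1.61, and the pericyte and muscle list the highest, 0.92.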

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

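The limma voom fit and the other splits of the libraries were chosen after the results were seen. The counts of 758 higher and 674 lower genes stayed within 1.5 times under the other pseudocounts, the minimum mean of 50 (611 and 524), rescaling to equal totals (657 and 799), quantile normalization (718 and 670), robust moderation (745 and 664) and voom (742 and 642, of which 736 and 640 were shared). With no filter they were 126 and 185, where 26782 genes were tested, and with a 2-fold minimum 317 and 390. Leaving out 1 library gave 146 to 2074 higher and 234 to 1993 lower genes: the lower numbers came with 1 resistant library and the higher with 1 control library, and the control pair had the wider spread. The MHC class I median was -0.25 to -0.37 over the 16 other settings run for that list. The list passed in these (adjusted p = 4.28e-06 to 0.0388, the highest with fry), except with an estimated correlation (-0.33, adjusted p = 0.564). A simulated list of independent genes, shifted downward, did not pass with an estimated correlation either (camera adjusted p = 0.238). Not passing that setting is therefore no evidence that a list was unchanged. The estimated correlation was -0.05 for the class I list, 0.52 for the type I interferon list and 0.20 for the interferon gamma list. As a replicate block, the numbers gave 628 higher and 585 lower genes (557 and 535 shared) and adjusted p = 0.00167 for the MHC class I list. The block ended the calls of 12 of 177 named genes, among them Tapbp, Psmb9, Erap1, Mcm3, Mcm4 and E2f1. They only name samples, and the deviations of same-numbered libraries correlated across genes with r = -0.357. No sign changed among the 127 named genes and 11 lists that passed with all libraries. For the genes this was fixed in advance where a library was left out, since the groups of all 1432 called genes did not overlap. The medians of 13 of the 21 other lists took both signs over the settings, such as proliferation (-0.18 to 0.14), Wnt (-0.25 to 0.06) and chemokines (-0.19 to 0.12), as did 6 of the 50 other named genes. Higher genes were 52.9% of the calls, 45.1% with equal totals, 40.5% without a filter and 35.3% to 56.3% with 1 library left out. 58 and 54 of 177 named genes lost their call without resistant replicate 1 and 2, and 66 without a filter, which tests more genes. The edgeR and DESeq2 fits planned for whole reads were not run. Genes with few reads are limited by depth. Of the 3 splits of the 4 libraries, 1, the real one, called 1432 genes and the highest other 0 (3764 and at most 438 at unadjusted p under 0.05, limma). So few splits cannot give a share under 0.05.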

Other observations

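The tests of leukocyte RNA, of scaling and of the class I heavy chains were chosen after the results were seen, and the genes of the first paragraph were picked after their values were seen. The tests on chromosomal position, GC content and single libraries were set before their results were seen.

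Some complement genes were lower in resistant cells. C3 (-1.49 ± 0.23, adjusted p = 0.00962), C4b (-3.00 ± 0.25, adjusted p = 0.000741) and C2 (-3.40 ± 0.23, adjusted p = 0.000415) fell in resistant cells, C4b from 4316 ± 1695 to 517 ± 55.7 normalized counts. The C1 proteases C1ra (0.08 ± 0.17) and C1s1 (0.07 ± 0.17) did not pass. Within the interferon pathway, Stat2 (-1.21 ± 0.11) and Irf9 (-1.16 ± 0.12) fell, whereas the receptor genes Ifnar1 (-0.16 ± 0.11), Ifnar2 (-0.16 ± 0.12), Ifngr1 (-0.40 ± 0.12) and Ifngr2 (-0.23 ± 0.11) and the kinase gene Jak1 (-0.20 ± 0.11) did not pass. 3 Ly6 genes of chromosome 15 fell, Ly6e, Ly6a and Ly6c1 (-3.19 ± 0.50, limma adjusted p = 0.00966). The other genes of that cluster that were looked up were not among the tested genes. Ly6a and Ly6c1 had means of 70.6 and 28.3 normalized counts in control cells and only 5.79 and 2.09 in resistant cells. The region did not fall as a whole: 150 genes at 70 to 80 Mb, the window of Ly6e, had a median of 0.19, with 28 higher and 8 lower.

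Interferon-stimulated genes were lower in the resistant libraries by a median of 1.55 on the log2 scale, over 75 genes. The tables argue against leukocyte RNA in the control libraries, since the largest control mean among 8 leukocyte transcripts was 4.39 normalized counts, against a median fall of 1193 in the interferon genes. The interferon median was -1.55 or lower under each of 3 scalings and on the reads with no scaling. Across these the median of all tested genes was only -0.08 to 0.002, so no scaling tried could have removed such a fall. After subtracting the other genes of each gene's 10 Mb window the interferon median was still -1.47. A lower interferon response of the resistant tumor cells is therefore a hypothesis consistent with these values. Whether the cells met less interferon or responded less was not tested. Both interferon transcripts examined were near the floor. Ifnb1 had 5.10 and 1.07 normalized counts in the resistant and 9.61 and 8.07 in the control libraries. Ifng had 6.11 in resistant replicate 1 and 0 in the other libraries.

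Neighbouring genes shifted together along chromosomes. The median log2 change was 0.21 over 577 genes of chromosome 15, with 90 higher and 15 lower calls. It was -0.23 over 493 genes of chromosome 19 (11 higher, 39 lower), -0.16 over 728 genes of chromosome 3 (15 and 67) and -0.14 over 436 genes of chromosome 16 (3 and 46). In a permutation over genes, 15 of 20 chromosomes had an adjusted p under 0.05, 7 upward and 8 downward, although neighbouring genes are not independent. GC content and transcript length leave 102% of the variance of 225 window medians after a smooth trend is removed, and window medians correlated with r = 0.736 between disjoint library pairs, against a drift of single libraries. Adjacent 10 Mb windows correlated with r = 0.773 (permutation p = 1e-04, the smallest that 10000 permutations can give), across windows that are not independent replicates. Large segments such as copy-number differences between the cell populations of the tumors may therefore contribute to the calls, a hypothesis that RNA alone leaves open. Among the lists, only the interferon and MHC class I lists were set against their windows. Single windows had larger shifts, such as 0.59 over 21 genes at 60 to 70 Mb of chromosome 15 and -0.27 over 103 genes at 80 to 90 Mb of chromosome 3. The chromosome 15 window holds Myc and Ndrg1. Calls in the other lists may therefore follow their neighbours.

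The MHC class I presentation list was lower by a median of 0.33. Shifts of whole windows do not account for it: relative to the other genes of their windows the median was -0.29. The window at 30 to 40 Mb of chromosome 17 holds 7 of the list, and 161 other genes there had a median of 0.02. A shift of a shorter segment around those 7 genes was not tested, since a value for the whole window cannot show it. Without H2-K1 and H2-D1, the BALB/c heavy chains aligned to another haplotype, the median was -0.33 as well, but removing any 2 of the 17 genes could have raised it no further than -0.32, so what their reads add to it cannot be told apart. The 4 genes that passed, Tap1, Tapbp, Psmb9 and Erap1, are not heavy chains. A small decrease of some class I genes in resistant cells remains a hypothesis, since 13 of the 17 did not pass and group and tumor of origin are confounded.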
